A study of Homo sapiens with 36 samples.

How the data were processed

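RNA from THP-1 cells treated in 12 groups of 3 libraries was sequenced by the submitters with a directional MGIEasy kit on an MGIseq instrument, as 100 bp paired-end reads from RNA with an integrity number above 7. Cells had been differentiated for 3 days with 100 ng/mL GM-CSF, 200 ng/mL IL-4, 20 ng/mL TNF-alpha and 200 ng/mL ionomycin and then treated for 24 h. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 with the hg38 genome, and give neither the annotation release nor the strand option. The deposited table holds RSEM expected counts for 60675 Ensembl gene IDs in 36 columns, and 9.78% of its cells are not whole numbers, so values were rounded. Depth was 29164455 to 49946327 counts per library.

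Gene symbols for 41209 IDs came from the supplied table of gene names. After SOD2 was found missing from its list, 15821 further symbols were taken from GENCODE v29, which also gave GRCh38 coordinates, and 3645 IDs have none (126 among the genes tested). Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 17776. One quasi-likelihood model with a mean per group was fitted to all 36 libraries with TMM scaling in R 4.3.3 (residual df 24), and 22 comparisons were tested with Benjamini-Hochberg adjustment at 0.05. SE values come from that model, and CPM values are means and SD of 3 libraries. TMM factors ranged from 0.967 to 1.06, and mitochondrial transcripts took 1.79% to 2.65% of counts.

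Comparisons were each treatment against vehicle, 500 against 125 for each extract, each ingredient at 500 against the mean of the other 3, the mixture against BJIKT at 500, and the mixture against the sum of the ingredient changes at 125. Samples were grouped by their GEO labels alone. The 3 codes in the descriptions are nested with treatments and could not be fitted as a term. In 17 comparisons 30 gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 510 tests, and again with a correlation estimated per list.

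The comparisons with their tests, the lists, the other settings first fitted and the rule for naming genes were fixed before the data were examined. The tests of the metallothionein explanations, the settings without the 2 atypical libraries, the tolerance for correlations and the conditions that left the code open for NF-kB targets and a swapped label open for astragalus 125 replicate 3 were set after values had been seen. The rule names the 6 largest rises and 6 largest falls among called genes in main comparisons, or 3 and 3 in the rest. It asks for groups that do not overlap, a mean of at least 5 CPM in the higher group and a symbol. It does not ask for separate groups in the mixture against the sum. It adds 3 called members with the smallest adjusted p from each of the 5 lists of at least 8 tested genes with the largest share called, and markers of dendritic cells fixed in advance. List members named beside a list's count but outside this rule were chosen after their values were seen. A gene that the rule names for the mixture against vehicle is not reported here.

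Correlations used all genes tested, and the value that a shared vehicle gives was simulated 20 times from unchanged groups. Ratios of low counts carry exact intervals, and a group with 0 counts was given a floor of 3 counts over the group. These intervals and floors cover counting error only. Alternatives were RLE and library-total scaling, no filter, a mean of at least 5 CPM, limma-voom, DESeq2 1.42.0, fits with only the compared libraries, each library left out and the replicate number as a block. The fit without astragalus 125 replicate 3 and BJIKT 125 replicate 2 and list medians with genes at their floor were added after the data were seen.

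The pipeline was tested on simulated data made for BJIKT 500 against vehicle, with 200 of 17590 genes changed. It called 23 of 50 genes changed 1.25-fold (46%), 40 of 50 at 1.5-fold (80%), 47 of 50 at 2-fold (94%) and 49 of 50 at 4-fold (98%), with 8 unchanged genes among 167 called. The random seed of this simulation was changed once after its first run, for a reason unrelated to its outcome. IL6, IL10 and IL12B were left out because their counts were too low to test. Transcript usage, allele and splice analyses were left out because only the deposited gene counts were used.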

Results

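Gene expression was measured by RNA sequencing in THP-1 cells, a human monocytic leukemia line. The cells had 3 days of GM-CSF, IL-4, TNF-alpha and ionomycin, are labeled mature dendritic cells, and were then treated for 24 h. The 12 groups of 3 libraries were PBS vehicle, the Bojungikki-tang (BJIKT) extract at 500 and 125 µg/mL, ginseng, astragalus, atractylodes and licorice extracts at the same 2 doses, and a mixture holding 125 µg/mL of each of these 4 ingredients. The 36 libraries held 29164455 to 49946327 counts each, and 17776 genes were tested. Each comparison sets 3 libraries against 3 unless stated otherwise, changes are log2 fold changes ± SE, and p is adjusted over all genes tested. Largest rises and falls are ranked only among called genes that have a symbol and a mean of at least 5 CPM in the higher group. In these, all libraries on one side of the comparison lay beyond all on the other. The comparison of the mixture with the sum of its ingredients had no such condition on libraries. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

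The astragalus 125 replicate 3 library stood apart from its 2 partners, at a root mean square log2 distance of 0.687 against 0.44 for the next library. Among genes picked after their values were seen, MT-ATP8, a subunit of the mitochondrial ATP synthase, had 0.195 CPM in it against 82.5 and 86.3 CPM in replicates 1 and 2. MIR155HG, the host gene of microRNA 155, had 0.973 CPM against 8.42 and 10.1. Its chemokine genes had a median deviation of -0.204 from the other 2 replicates, while class I antigen presentation genes had 0.231 (13 of 17 above 0) and marker genes of other cell types 0.371 (7 of 7 above 0). The sample descriptions carry 3 codes of 12 libraries each, whose meaning is not stated. Outside astragalus 125, the library furthest from its partners was BJIKT 125 replicate 2, at 0.404. Astragalus 125 replicates 1 and 2 lay further, but replicate 3 is among their partners. Fits without BJIKT 125 replicate 2 and astragalus 125 replicate 3 are called fits without the 2 atypical libraries. Vehicle replicate 3 did not lie far from its partners (0.332), but it enters every comparison with vehicle. For most of these, leaving it out gave the lowest count of called genes among fits that left out a library. Atractylodes 125 then had 5 genes, against 29 and 28 without vehicle replicates 1 and 2. Vehicle shares its code with both BJIKT groups and ginseng 500, so the comparison of every other treatment with vehicle crosses codes. Atractylodes 125, in the code of the mixture and both licorice groups, differed from vehicle in 32 genes, against 3673 for the mixture and 6605 for licorice 500, but for small changes the code and the treatment cannot be told apart. The dose comparisons of ginseng and atractylodes, each ingredient against the other 3 and the mixture against BJIKT also cross codes, while the doses of BJIKT, astragalus and licorice lie within 1 code.

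To ask what the prescription changes at its higher dose, BJIKT 500 was compared with vehicle, and the largest rises were in chemokine and cytokine genes. CXCL2 (ENSG00000081041, chromosome 4, 74097035 to 74099293), whose product attracts neutrophils, rose by 4.89 ± 0.11, from 3.61 ± 0.34 to 107.8 ± 7.26 CPM (mean ± SD, n = 3 and 3, adjusted p = 8.58e-25). IL1B (ENSG00000125538, chromosome 2, 112829751 to 112836903), which encodes interleukin-1 beta, rose by 4.04 ± 0.06, from 11.4 ± 0.44 to 187.7 ± 6.43 CPM (adjusted p = 1.50e-29). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716), which encodes interleukin-8, rose by 3.86 ± 0.12, from 331.7 ± 28.0 to 4805.1 ± 68.8 CPM (adjusted p = 3.82e-21). TNF, encoding tumor necrosis factor, rose by 3.27 ± 0.07 and LIF, a cytokine of the interleukin-6 family, by 3.01 ± 0.11. CXCL1 rose by 4.77 ± 0.21 and CXCL3 by 4.24 ± 0.15, but these 2 genes resemble CXCL2 in sequence, so how reads divide among the 3 is uncertain. Among genes that met the naming rule, the largest falls were in SDS (ENSG00000135094, chromosome 12, 113392445 to 113426301), a serine dehydratase, by 2.15 ± 0.11, and RNF125, a ubiquitin ligase, by 2.14 ± 0.14. SASH3, an adaptor of immune cell signaling, fell by 2.06 ± 0.09, ENC1, an actin-binding protein, by 1.70 ± 0.11, and SLA, an adaptor that dampens receptor signaling, by 1.43 ± 0.08. FCGR1BP, a pseudogene close to FCGR1A in sequence and so uncertain, fell by 1.37 ± 0.10. In total 4517 of 17776 genes (25.4%) were called, 2130 higher and 2387 lower, and 518 of them changed at least 2-fold. With libraries scaled to their totals in place of TMM, 1694 were higher and 2943 lower, so the share higher moved from 47.2% to 36.5%.

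**Figure D1:**
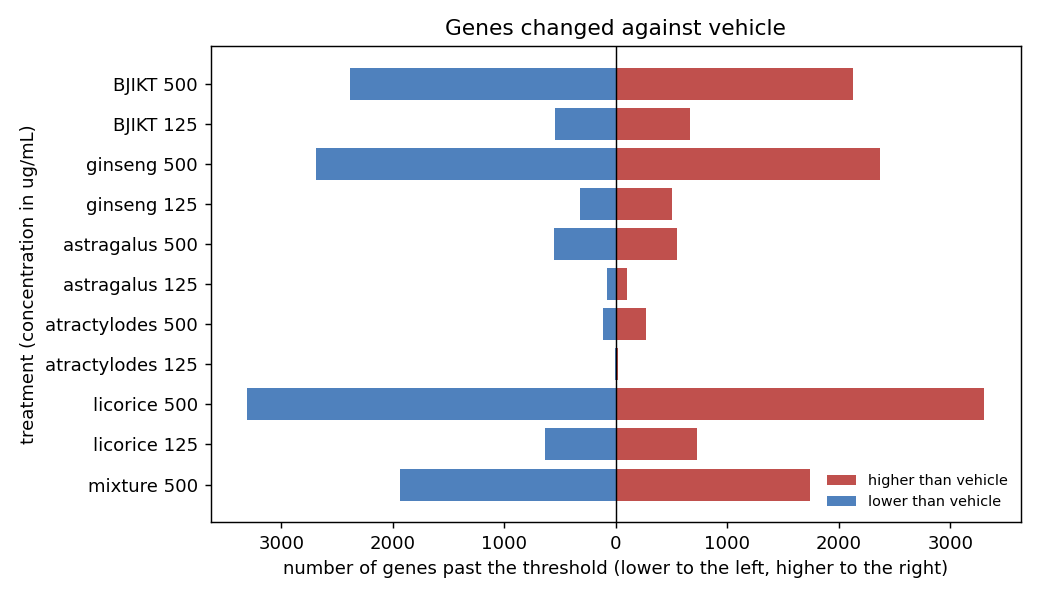
Number of genes higher and lower than vehicle for each treatment and dose (3 libraries against 3, edgeR, adjusted over 17776 genes).

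Among groups of genes after BJIKT 500, NF-kB targets rose in 23 of 24 and fell in 1, over all genes and adjusted over the list alone (median 1.3, camera adjusted p = 9.4e-36). NFKBIZ, a co-activator of cytokine genes, rose by 2.90 ± 0.07, ZC3H12A, an RNase that limits cytokine mRNA, by 2.697 ± 0.081, and TNFAIP3, which restrains NF-kB signaling, by 1.35 ± 0.04, whereas the survival gene BCL2A1 fell by 0.82. Chemokine genes split 13 higher and 3 lower by either adjustment (median 2.3, adjusted p = 7.6e-13). CCL20, which attracts dendritic cell precursors, rose by 4.06, and the monocyte attractants CCL2, CCL8 and CCL13 fell by 0.94, 0.75 and 0.64. Of 15 cytokine genes 10 rose and 3 fell, or 4 adjusted over the list alone (median 0.69, adjusted p = 4.0e-08), and IL18 and TNFSF13B were among those that fell. Dendritic cell maturation genes rose in 18 of 22 and fell in 1 (19 and 1 adjusted over the list alone, median 0.56, adjusted p = 1.5e-13). EBI3, a subunit of interleukins 27 and 35, rose by 2.76 ± 0.08 and the co-stimulatory gene CD80 by 2.60 ± 0.14. CCR7, the receptor for homing to lymph nodes, rose by 1.65 ± 0.23. The vehicle levels were low, at 0.8083 to 1.126 CPM for CD80 and 0.6235 to 1.368 CPM for CCR7. CD274, which encodes PD-L1, rose by 0.91 ± 0.06, CD40 by 0.59 ± 0.06 and the maturation marker CD83 by 0.48 ± 0.05. CD86, the other ligand of CD28, was the member that fell, by 0.61 ± 0.07. Immediate early genes rose in 20 of 25 and fell in 1 by either adjustment (median 0.55, adjusted p = 9.3e-18), among them IER3 by 2.28 ± 0.07 and DUSP1 by 0.98 ± 0.06, and MYC fell by 0.31.

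Aryl hydrocarbon receptor targets rose in 6 of 7 by either adjustment after BJIKT 500 (median 0.57, adjusted p = 4.5e-08), with CYP1B1, a cytochrome that metabolizes aromatic compounds, at 1.09 and TIPARP, a feedback inhibitor of the receptor, at 0.89. NRF2 targets rose in 10 of 24 and fell in 2 (11 and 2 adjusted over the list alone, median 0.13, adjusted p = 0.0005), with heme oxygenase HMOX1 at 0.79. Glucocorticoid receptor targets rose in 5 of 11 and fell in 1 by either adjustment (median 0.38, adjusted p = 0.0056), but TSC22D3, the classical member, was the one that fell. Lysosome and phagocytosis genes fell in 15 of 26 and rose in 4 (16 and 4 adjusted over the list alone, median -0.2, adjusted p = 2.4e-05), among them the lipase LIPA by 0.56 and cathepsin D, CTSD, by 0.43. LXR and PPAR lipid targets fell in 9 of 22 and rose in 2 (10 and 2, median -0.24, adjusted p = 0.0036). PLIN2, which coats lipid droplets, fell by 0.98, whereas ABCA1, the cholesterol exporter, rose by 1.01. Markers of undifferentiated leukemia cells fell in 6 of 9 by either adjustment (median -0.36, adjusted p = 0.0027), ELANE and MYB among them.

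A further 5 lists were called after BJIKT 500 with the preset correlation only. Class I antigen presentation genes rose in 9 of 17, TAP1 by 0.47 (10 adjusted over the list alone, median 0.16, adjusted p = 6.4e-05, adjusted p = 0.079 with an estimated correlation). Genes of the IL-4 response fell in 9 of 19 and rose in 4 (10 and 4, median -0.26, adjusted p = 0.011, adjusted p = 0.095 with an estimated correlation), F13A1, the transglutaminase factor XIII A, by 2.85. F13A1 did not meet the naming rule. Metallothionein and metal response genes rose in 5 of 9 and fell in 2 by either adjustment (median 0.36, adjusted p = 0.043, adjusted p = 0.18 with an estimated correlation). That median is 0.89 without MT1M, which had 0 counts in both groups. Iron handling genes rose in 6 of 14 and fell in 2 (6 and 3, median 0.17, adjusted p = 0.039, adjusted p = 0.055 with an estimated correlation), and the transferrin receptor TFRC fell by 0.40. Monocyte and macrophage markers fell in 6 of 15 and rose in 1 by either adjustment (median -0.19, adjusted p = 0.0078, adjusted p = 0.055 with an estimated correlation), with CD14 the one that rose, by 0.32 ± 0.08.

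The remaining lists were not called after BJIKT 500. Type I interferon genes were higher in 5 of 28 and lower in 2 by either adjustment (median 0.011, adjusted p = 0.48), with RSAD2 at 0.92 and MX1 at -0.25. Class II antigen presentation genes were higher in 1 of 14 and lower in 3 (median -0.053, adjusted p = 0.43). HLA-DRA was not called at 0.16 ± 0.14 (adjusted p = 0.486), and was low throughout, at 2.303 to 3.777 CPM over the 36 libraries. Dendritic cell identity genes were higher in 4 of 14 and lower in 5 (median -0.26, adjusted p = 0.58), with CD209 at -0.38 ± 0.06 and IRF4 at 0.96. Pattern recognition genes were higher in 9 of 22 and lower in 6 (median 0.05, adjusted p = 0.26), with TLR1 at 0.89 and TLR4 at -1.14. Sterol synthesis genes were higher in 5 of 24 and lower in 3 (median 0.021, adjusted p = 0.46), and unfolded protein response genes higher in 3 of 20 and lower in 2 (median 0.082, adjusted p = 0.46). Integrated stress response genes were higher in 7 of 24 and lower in 5 (7 and 6 alone, median -0.00025, adjusted p = 0.81). Heat shock genes were higher in 3 of 15 and lower in 4 (3 and 6 alone, median -0.096, adjusted p = 0.41). Hypoxia and glycolysis genes were higher in 6 of 29 and lower in 7 (median -0.0043, adjusted p = 0.74), and p53 targets higher in 5 of 20 and lower in 2 (median 0.067, adjusted p = 0.17). Cell cycle genes were higher in 3 of 29 (2 alone, median 0.0049, adjusted p = 0.92). Matrix and migration genes were higher in 9 of 22 and lower in 9 (10 and 9 alone, median 0.11, adjusted p = 0.6). Mitochondrially encoded transcripts (0 of 13, adjusted p = 0.77) and markers of other cell types (0 and 1 of 7, adjusted p = 0.11) had medians of 0.045 and -0.21. Median, mean and test differed in sign for the stress response, hypoxia and cell cycle lists. IL6, IL10 and IL12B had at most 2, 5 and 4 counts in any library and were not tested.

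At 125 µg/mL BJIKT raised CXCL2 by 3.41 ± 0.11, CXCL8 by 2.19 ± 0.11 and IL1B by 2.16 ± 0.06 (n = 3 and 3), and SDS fell by 0.89 ± 0.10, RNF125 by 0.84 ± 0.12 and ENC1 by 0.79 ± 0.10. The count was 1214 genes, 664 higher and 550 lower, but 513 when only these 6 libraries were fitted, 740 without vehicle replicate 3 and 741 without BJIKT 125 replicate 2. Library totals as scale moved the share higher from 54.7% to 40.4%. Of 24 NF-kB targets 18 rose (23 higher and 1 lower adjusted over the list alone, median 0.64, adjusted p = 4.8e-48). Maturation genes rose in 11 of 22 and fell in 1 (17 and 1, median 0.3, adjusted p = 5.7e-12), and aryl hydrocarbon receptor targets rose in 5 of 7 (median 0.54, adjusted p = 1.3e-11). To ask whether dose matters, 500 was compared with 125: CXCL3 was higher by 2.02 ± 0.12, IL1B by 1.88 ± 0.05 and the antisense gene SLC30A4-AS1, uncertain because the strand used in counting is not stated, by 1.73 ± 0.14. SASH3 was lower by 1.31 ± 0.09, SDS by 1.26 ± 0.12 and CD80 was higher by 1.71 ± 0.12. Of 2715 genes that differed by dose, 1298 were higher and 1417 lower at 500, and the count was 1808 without BJIKT 125 replicate 2. Lysosome genes were lower at 500 in 13 of 26 and higher in 1 (15 and 1, median -0.19, adjusted p = 3.9e-07).

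**Figure D2:**
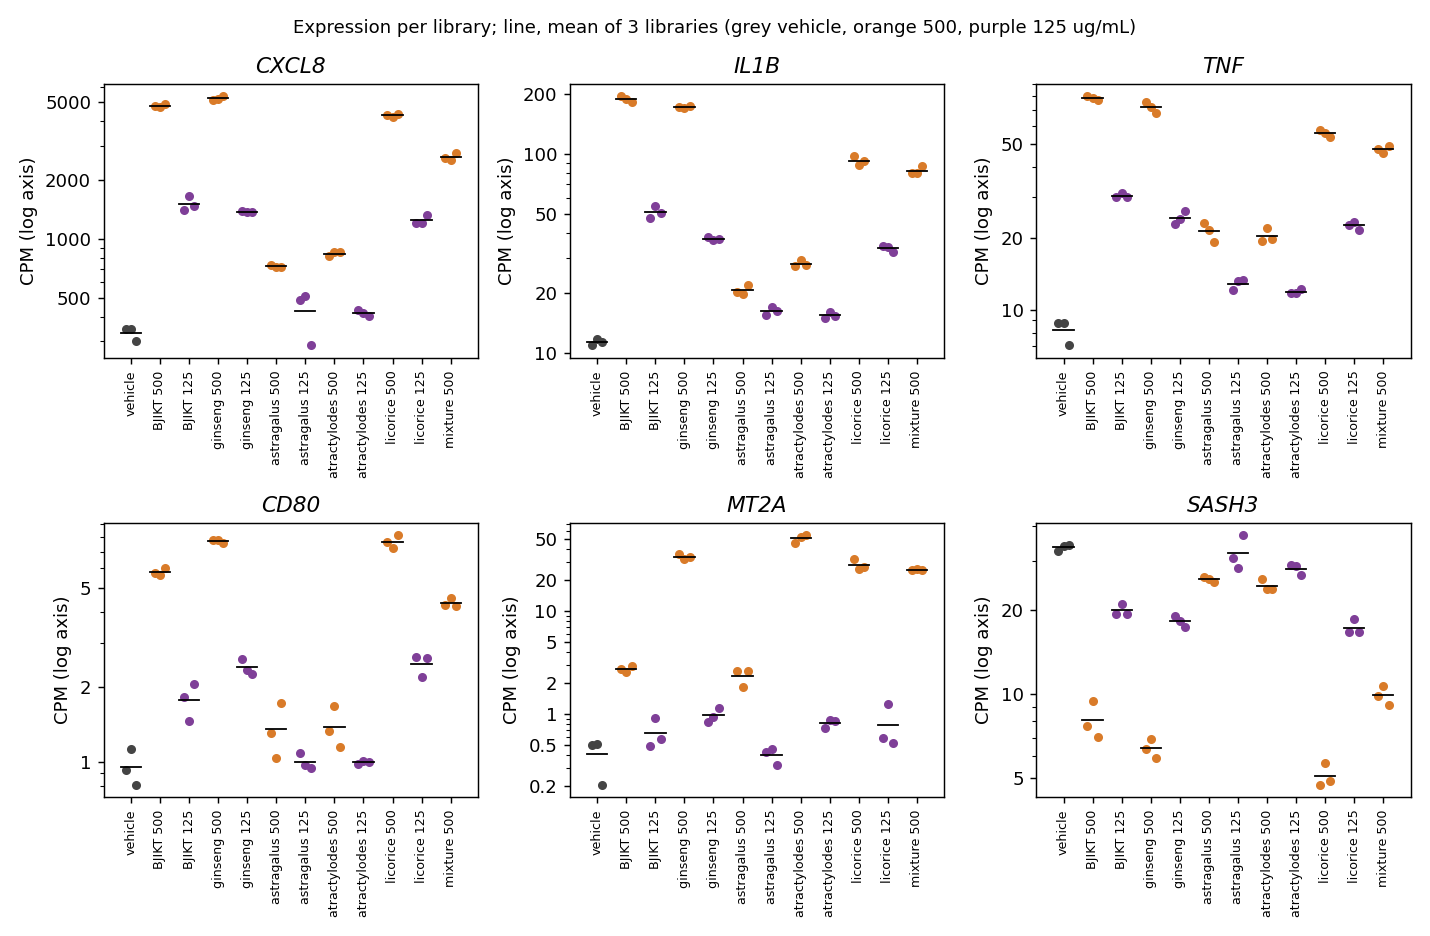
CPM of CXCL8, IL1B, TNF, CD80, MT2A and SASH3 in each of the 36 libraries on a log axis, with the mean of 3 libraries as a line.

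Ginseng 500 was compared with vehicle to ask what this ingredient changes alone, and metallothionein genes, which bind zinc and copper, led its rises. MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497) rose by 6.40 ± 0.19, from 0.409 ± 0.174 to 33.7 ± 1.82 CPM (n = 3 and 3, adjusted p = 1.01e-21). MT1E rose by 6.01 ± 0.24 and MT1X by 5.54 ± 0.21, but MT1 and MT2 genes resemble each other, so how reads divide among them is uncertain. The chemokine CCL15, which attracts monocytes and T cells, rose by 6.00 ± 0.44, at 677 counts against 10 in vehicle, a ratio of 63.7 with a 95% counting interval of 34.4 to 133.3 that covers counting error only. CXCL2 rose by 5.19 ± 0.11, CXCL1 by 4.88 ± 0.21 and CCL20 by 4.81 ± 0.16. SASH3 (ENSG00000122122, chromosome X, 129779979 to 129795201) fell by 2.39 ± 0.09 (adjusted p = 6.42e-19). SDS fell by 2.03 ± 0.11, ENC1 by 2.02 ± 0.12, RNF125 by 1.92 ± 0.14, the sorting receptor SORL1 by 1.70 ± 0.12 and SYTL1, a vesicle transport protein, by 1.61 ± 0.10. The count was 5065 genes, 2371 higher and 2694 lower, and library totals as scale gave 1811 higher and 3538 lower, 33.9% higher in place of 46.8%. Metallothionein and metal response genes rose in 7 of 9, the transcription factor MTF1 among them by 0.404, and SLC39A10, a zinc importer, fell (median 5.5, adjusted p = 3.0e-08). MT1M had 0 counts in vehicle and was at least 6.51-fold higher, and with it at that bound the list median is 2.7.

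Chemokine genes split 13 higher and 3 lower of 16 after ginseng 500 by either adjustment (median 2.4, adjusted p = 2.7e-13). NF-kB targets split 23 and 1 of 24 (median 1.4, adjusted p = 3.6e-33) and immediate early genes 20 and 1 of 25 (median 0.62, adjusted p = 2.0e-17), again by either adjustment. Maturation genes rose in 18 of 22 and fell in 1 (19 and 1, median 0.64, adjusted p = 5.9e-14). EBI3 was at 3.30 ± 0.08, CD80 at 3.02 ± 0.14, CCR7 at 2.29 ± 0.22, CD274 at 1.04 ± 0.06 and CD83 at 0.68 ± 0.05, while CD86 fell by 0.67 ± 0.07. Cytokine genes rose in 9 of 15 and fell in 3 (9 and 4, median 0.99, adjusted p = 1.6e-06), with TNF at 3.13 ± 0.07. Aryl hydrocarbon receptor targets rose in 5 of 7 (6 higher and 1 lower alone, median 0.44, adjusted p = 8.6e-06). NRF2 targets rose in 11 of 24 and fell in 1 (12 and 2 alone, median 0.18, adjusted p = 0.00019). Glucocorticoid receptor targets rose in 7 of 11 and fell in 2 (median 0.42, adjusted p = 0.0016), and iron genes rose in 6 of 14 and fell in 2 (median 0.16, adjusted p = 0.014). Lysosome genes fell in 13 of 26 and rose in 4 (median -0.14, adjusted p = 0.0015), and LXR and PPAR targets fell in 8 of 22 and rose in 2 (median -0.2, adjusted p = 0.037). Monocyte markers fell in 6 of 15 (7 alone, median -0.25, adjusted p = 0.0023) and leukemia cell markers in 6 of 9 (median -0.5, adjusted p = 0.00054). With the preset correlation only, 3 more lists were called. Class I genes rose in 9 of 17 (median 0.14, adjusted p = 0.0018, adjusted p = 0.17 with an estimated correlation). Unfolded protein response genes fell in 10 of 20 and rose in 2 (median -0.19, adjusted p = 0.0028, adjusted p = 0.087 with an estimated correlation). IL-4 response genes fell in 10 of 19 and rose in 5 (11 and 6 alone, median -0.37, adjusted p = 0.036, adjusted p = 0.17 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.36.

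Ginseng 125 raised CXCL2 by 3.28 ± 0.11, CXCL8 by 2.06 ± 0.11 and ZC3H12A by 1.84 ± 0.08, and ENC1 fell by 0.90 ± 0.10, SASH3 by 0.88 ± 0.08 and SDS by 0.75 ± 0.10. Its count was 827 genes, 502 higher and 325 lower, but 1255 with only these 6 libraries, 1936 without the 2 atypical libraries and 526 without vehicle replicate 3. NF-kB targets rose in 19 of 24 and fell in 1 (21 and 1 alone, median 0.69, adjusted p = 2.1e-54). Between the 2 doses MT1E was higher at 500 by 5.23 ± 0.20, MT2A by 5.10 ± 0.16 and MT1X by 4.38 ± 0.17, and SASH3 was lower by 1.51 ± 0.09, SDS by 1.29 ± 0.11 and SYTL1 by 1.13 ± 0.10. The dose comparison called 2771 genes, 1300 higher and 1471 lower, and 4979 with only its 6 libraries or 4825 without the 2 atypical libraries. Library totals as scale moved its share higher from 46.9% to 34.5%. Chemokine genes were higher at 500 in 13 of 16 and lower in 2 (13 and 3 alone, median 1.4, adjusted p = 8.1e-18).

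Astragalus 500, asked the same question, raised EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315), an immediate early transcription factor, by 1.72 ± 0.13, from 3.86 ± 0.55 to 12.7 ± 0.90 CPM (n = 3 and 3, adjusted p = 1.03e-10). TNF rose by 1.39 ± 0.07, CXCL2 by 1.34 ± 0.12, TNFAIP6, a hyaluronan-binding protein, by 1.16 ± 0.10, CXCL8 by 1.13 ± 0.11, NFKBIZ by 1.11 ± 0.07 and IL1B by 0.86 ± 0.06. PGBD5, a domesticated transposase, fell by 0.76 ± 0.08, LRRC25, a membrane protein of myeloid cells, by 0.76 ± 0.12, SDS by 0.73 ± 0.10 and RASGRP3, a Ras activator, by 0.72 ± 0.07. FGD6, a protein with a FYVE domain, fell by 0.64 ± 0.13 and PPP1R27, a phosphatase regulator, by 0.64 ± 0.15, the latter not called without vehicle replicate 3 (adjusted p = 0.0585). CD86 fell by 0.28 ± 0.06 (not called in 2 of 6 fits that left out a library, adjusted p = 0.101 and 0.0599). CD80 was not called at 0.49 ± 0.17 (adjusted p = 0.0758). It was called without astragalus 500 replicate 2 (0.664, adjusted p = 0.0251) and without the 2 atypical libraries (0.491, adjusted p = 0.0407). The count was 1100 genes, 546 higher and 554 lower, 2086 with only these 6 libraries, 3014 without the 2 atypical libraries, and 628 to 767 with any library left out. Its split moved both ways, to 581 higher and 396 lower with library totals as scale (59.5% higher in place of 49.6%) and 518 and 726 by DESeq2. Of 24 NF-kB targets 12 rose and BCL2A1 fell (14 and 1 alone, median 0.18, adjusted p = 1.3e-13), and chemokine genes rose in 7 of 16 (8 alone, median 0.79, adjusted p = 1.6e-07).

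Cytokine genes rose in 5 of 15 and fell in 1 after astragalus 500 (6 and 1 alone, median 0.1, adjusted p = 0.00055), CSF1 by 0.38 ± 0.08. Metallothionein and metal response genes rose in 4 of 9 (4 and 1 lower alone, median 0.26, adjusted p = 0.00011), MT2A by 2.54 ± 0.27, and the median is 1.38 without MT1M, at 0 counts in vehicle. Of the 7 aryl hydrocarbon receptor targets 1 rose, IL1B (median 0.13, adjusted p = 0.0015). IL1B is also a member of the cytokine list, here and in every comparison, so calls of these lists are not independent. Lysosome genes fell in 5 of 26 (8 alone, median -0.072, adjusted p = 0.00054) and hypoxia and glycolysis genes in 8 of 29, with 1 higher (11 and 2 alone, median -0.086, adjusted p = 1.5e-06), LDHA by 0.28 among them. A further 7 lists were called with the preset correlation only. Immediate early genes rose in 6 of 25 (8 higher and 2 lower alone, median 0.068, adjusted p = 9.1e-05, adjusted p = 0.14 with an estimated correlation). Mitochondrially encoded transcripts rose in 2 of 13 (7 alone, median 0.23, adjusted p = 8.1e-05, adjusted p = 0.25 with an estimated correlation). Of the sterol genes 1 of 24 rose (median 0.066, adjusted p = 0.02, adjusted p = 0.19 with an estimated correlation). Of the class I genes 1 of 17 rose (median 0.058, adjusted p = 0.03, adjusted p = 0.34 with an estimated correlation). NRF2 targets rose in 5 of 24 and fell in 3 (6 and 4 alone, median 0.066, adjusted p = 0.034, adjusted p = 0.12 with an estimated correlation). AKR1C1 rose by 0.66 ± 0.09, but it resembles AKR1C2 and AKR1C3 in sequence and its value is uncertain. Heat shock genes fell in 3 of 15 (5 alone, median -0.065, adjusted p = 0.00054, adjusted p = 0.082 with an estimated correlation). IL-4 response genes fell in 5 of 19 (6 alone, median -0.029, adjusted p = 0.021, adjusted p = 0.13 with an estimated correlation). Median, mean and test differed in sign for uncalled lists of dendritic cell identity, pattern recognition, p53, monocyte, leukemia and matrix genes.

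Astragalus 125 called 181 genes, 101 higher and 80 lower, by edgeR, where 3536 had an unadjusted p under the same level. EGR1 rose by 0.96 ± 0.13, CCL3L3 by 0.71 ± 0.11 and CCL3, which resembles it and so is uncertain, by 0.69 ± 0.10. The cytokine TNFSF15, the inositol transporter SLC5A3 and the pseudogene ANXA2P2 fell by 0.53 ± 0.13, 0.53 ± 0.12 and 0.52 ± 0.11, and lost their calls in 3, 2 and 1 of 6 fits that left out a library. SLC5A3 had 503.2 CPM in replicate 3, against 905.7 and 910.5 in replicates 1 and 2. No gene was called with only these 6 libraries by edgeR (0, each named gene at adjusted p = 0.854). The count was 642 by DESeq2, 524 without the 2 atypical libraries, 362 at a stricter expression filter, 920 with no filter, 46 without vehicle replicate 3 and 2534 without astragalus 125 replicate 2. The split was not stable, at 177 higher and 70 lower with library totals as scale (71.7% higher in place of 55.8%), 89 and 120 with RLE factors (42.6%), 165 and 477 by DESeq2 and 181 and 739 with no filter. Of 24 NF-kB targets 6 rose (10 and 1 lower alone, median 0.12, adjusted p = 5.3e-07), but replicate 3, which stood apart, deviated from the other 2 by a median of 0.0813 on this list (14 of 24 above 0). Across genes the change from vehicle followed GC content at a Spearman correlation of 0.441, and the dose difference at -0.536. The 2 doses differed in 319 genes, 139 higher and 180 lower at 500, of 3940 with an unadjusted p under the same level. CXCL2 was higher by 0.82 ± 0.11, CXCL8 by 0.76 ± 0.11 and EGR1 by 0.75 ± 0.12, and the ion channel TRPA1, the pseudogene FABP5P7 and SDS were lower by 0.98 ± 0.25, 0.59 ± 0.14 and 0.54 ± 0.10. CXCL8 lay at 489.9, 513.9 and 286.4 CPM in astragalus 125 replicates 1, 2 and 3, so replicate 3 enlarged its dose difference. Without the 2 atypical libraries edgeR called CXCL8 higher than vehicle at 125 µg/mL (0.592, adjusted p = 6.52e-10). TRPA1 was at -0.37 (adjusted p = 0.402) and FABP5P7 at -0.455 (adjusted p = 0.0769) without the 2 atypical libraries, and they lost their calls in 4 and 3 of 6 fits that left out a library. The dose count was 0 with only these 6 libraries, 186 without the 2 atypical libraries, 505 at the stricter filter, 717 by DESeq2, 1192 with no filter and 53 to 3399 with any library left out. Its split turned to 989 higher and 203 lower with no filter, 1528 and 731 without astragalus 125 replicate 1 and 2321 and 1078 without replicate 2.

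Atractylodes 500 raised metallothionein genes most. MT2A rose by 7.00 ± 0.19, from 0.409 ± 0.174 to 51.1 ± 4.20 CPM (n = 3 and 3, adjusted p = 3.34e-22), MT1E by 6.63 ± 0.23 and MT1X by 6.07 ± 0.20. MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065) rose by 7.75 ± 0.33, at 999 counts against 4, a ratio of 233.4 with a 95% counting interval of 90.9 to 858.1. CXCL2 rose by 1.92 ± 0.11, CXCL8 by 1.34 ± 0.11, TNF by 1.33 ± 0.07 and IL1B by 1.298 ± 0.058. BCL11A, a repressor of transcription, fell by 0.66 ± 0.12, RNF125 by 0.59 ± 0.12, SDS by 0.57 ± 0.10, PPP1R27 by 0.56 ± 0.15, FCGR1BP by 0.54 ± 0.09 and SLC39A10 by 0.51 ± 0.11. Without vehicle replicate 3, SLC39A10 (adjusted p = 0.144) and RNF125 (-0.48, adjusted p = 0.103) were not called. SLC39A10 was also lost without atractylodes 500 replicate 3 (-0.501, adjusted p = 0.0542). PPP1R27 was lost in 4 of the 6 fits that left out a library (adjusted p = 0.0964 to 0.301). CD86 (-0.15, adjusted p = 0.355), CD80 (0.54, adjusted p = 0.0919) and CD83 (0.09, adjusted p = 0.579) were not called. CD80 gained a call without the 2 atypical libraries (0.542, adjusted p = 0.0382). The count was 384 genes, 267 higher and 117 lower, 736 with only these 6 libraries, 1226 without the 2 atypical libraries, 170 without vehicle replicate 3 and 237 to 253 without a library of its own.

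After atractylodes 500, metallothionein and metal response genes rose in 6 of 9 and SLC39A10 fell (median 6.1, adjusted p = 9.8e-29). MT1M was at least 10.0-fold higher, and with it at that bound the list median is 3.32. Of 24 NF-kB targets 15 rose and BCL2A1 fell (19 and 1 alone, median 0.4, adjusted p = 8.5e-39). Immediate early genes rose in 12 of 25 (19 alone, median 0.23, adjusted p = 4.4e-22) and chemokine genes in 8 of 16 (9 alone, median 0.82, adjusted p = 3.0e-14). Aryl hydrocarbon receptor targets rose in 5 of 7 by either adjustment (median 0.46, adjusted p = 5.1e-17), CYP1B1 by 0.53, TIPARP by 0.49 and AHRR, a repressor of the receptor, by 0.30. Cytokine genes rose in 4 of 15 (5 alone, median 0.065, adjusted p = 3.6e-06), maturation genes in 2 of 22 (4 alone, median 0.11, adjusted p = 1.5e-05) and NRF2 targets in 2 of 24 (6 alone, median 0.096, adjusted p = 0.00022). Lysosome genes fell in 2 of 26 (3 alone, median -0.083, adjusted p = 8.4e-05). With the preset correlation only, 4 more lists were called. Mitochondrially encoded transcripts had 0 of 13 called (3 alone, median 0.23, adjusted p = 4.2e-06, adjusted p = 0.18 with an estimated correlation). Unfolded protein response genes rose in 2 of 20 (5 alone, median 0.064, adjusted p = 0.0058, adjusted p = 0.11 with an estimated correlation). Glucocorticoid receptor targets rose in 2 of 11 (2 higher and 1 lower alone, median 0.11, adjusted p = 0.022, adjusted p = 0.05 with an estimated correlation). Of the monocyte markers 1 of 15 fell (median -0.11, adjusted p = 0.024, adjusted p = 0.11 with an estimated correlation). Median, mean and test differed in sign for uncalled lists of dendritic cell identity, interferon, stress response, cell cycle, other cell type and matrix genes.

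Atractylodes 125 called 32 genes, 23 higher and 9 lower, of 1415 with an unadjusted p under the same level. TNF rose by 0.55 ± 0.08, IL1B by 0.44 ± 0.06 and the mitochondrial pseudogene MTATP6P1, uncertain, by 0.51 ± 0.08. The antisense genes NFYC-AS1 and KCNQ1OT1, both uncertain, fell by 0.54 ± 0.09 and 0.49 ± 0.11, and the carboxypeptidase PRCP by 0.22 ± 0.05. NFYC-AS1 lay at 11.12 to 13.63 CPM in all 12 libraries of the atractylodes 125 code, licorice and mixture included. With atractylodes 500 it lay at 17.15 to 18.08, and elsewhere only astragalus 125 replicate 3 was as low. KCNQ1OT1 was at 10.29 to 13.53 in that code and 15.29 to 16.03 with atractylodes 500, with some overlap from other codes. Both falls may thus follow the code and not the extract. KCNQ1OT1, PRCP, MTATP6P1 and NFYC-AS1 lost their calls in 6, 5, 2 and 1 of the 6 fits that left out a library. KCNQ1OT1 and PRCP also lost theirs with library totals as scale and with the replicate block. The count was 84 with only these 6 libraries, 229 without the 2 atypical libraries, 66 by DESeq2, 89 with no filter and 5 to 29 with any library left out. Aryl hydrocarbon receptor targets rose in 4 of 7 (5 alone, median 0.29, adjusted p = 2.6e-10) and NF-kB targets in 2 of 24 (8 and 1 lower alone, median 0.12, adjusted p = 1.3e-09). Between doses, MT2A was higher at 500 by 5.95 ± 0.16, MT1G by 5.52 ± 0.25 and MT1E by 5.51 ± 0.20. SDS, the melanophilin gene MLPH and SKIDA1, a nuclear protein, were lower by 0.46 ± 0.10, 0.45 ± 0.09 and 0.41 ± 0.09. SKIDA1 lost its call whichever library was left out, and SDS in 5 of 6 such fits (adjusted p = 0.0645 to 0.126). The dose comparison called 101 genes, 80 higher and 21 lower, 409 with only its 6 libraries, 434 without the 2 atypical libraries and 57 to 67 with any library left out. NF-kB targets were higher at 500 in 11 of 24 (13 and 1 lower alone, median 0.27, adjusted p = 1.5e-29).

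Licorice 500 gave the largest count of any treatment, and metallothionein and chemokine genes led the rises. MT2A rose by 6.15 ± 0.19, from 0.409 ± 0.174 to 28.4 ± 3.29 CPM (n = 3 and 3, adjusted p = 3.79e-21), MT1E by 5.77 ± 0.24 and MT1X by 5.28 ± 0.21. CXCL2 rose by 4.85 ± 0.11, CXCL1 by 4.53 ± 0.21 and CXCL8 by 3.69 ± 0.12. SASH3 fell by 2.71 ± 0.10. SCIMP (ENSG00000161929, chromosome 17, 5208961 to 5234860), an adaptor for toll-like receptor and class II signaling, fell by 2.55 ± 0.10, from 10.1 ± 0.06 to 1.72 ± 0.22 CPM (adjusted p = 6.26e-19). SLA fell by 2.27 ± 0.09, ENC1 by 2.19 ± 0.12, SLAMF8, a receptor that curbs macrophage oxidative burst, by 1.96 ± 0.07 and FGL2, a secreted immune suppressor, by 1.93 ± 0.18. The count was 6605 genes (37.2%), 3300 higher and 3305 lower, 829 of them by at least 2-fold. Maturation genes rose in 15 of 22 and fell in 4 (16 and 4 alone, median 0.5, adjusted p = 8.5e-07). CD80 was at 3.01 ± 0.14, EBI3 at 2.66 ± 0.08, LAMP3, a lysosomal protein of mature dendritic cells, at 2.13 ± 0.09 and CCR7 at 1.248 ± 0.235, while CD86 fell by 1.04 ± 0.07. Unfolded protein response genes rose in 16 of 20 (17 and 1 lower alone, median 0.33, adjusted p = 2.8e-08), HSPA5 by 0.86 and HYOU1, another chaperone, by 0.79. Integrated stress response genes rose in 11 of 24 and fell in 4 (12 and 4 alone, median 0.22, adjusted p = 0.0079).

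After licorice 500, 20 of 24 NF-kB targets rose and BCL2A1 fell by 1.73 (same counts alone, median 1.1, adjusted p = 1.3e-21). Chemokine genes split 10 higher and 3 lower of 16 (same counts alone, median 1.2, adjusted p = 6.6e-05) and cytokine genes 9 and 3 of 15 (10 and 3 alone, median 0.81, adjusted p = 1.8e-05). IL23A, a subunit of interleukin-23, rose by 2.34 ± 0.15. Metallothionein and metal response genes rose in 6 of 9 and SLC39A10 fell (median 5.3, adjusted p = 4.8e-05). MT1M was at least 7.43-fold higher, and with it at that bound the list median is 2.89. IL-4 response genes fell in 14 of 19 and CCL17 rose (same counts alone, median -0.47, adjusted p = 1.0e-05), F13A1 by 3.26 and ALOX15, a lipoxygenase induced by IL-4, by 1.37. Lysosome genes fell in 16 of 26 and rose in 3 (17 and 3 alone, median -0.24, adjusted p = 3.5e-05), and matrix genes fell in 11 of 22 and rose in 4 (12 and 4 alone, median -0.26, adjusted p = 0.0021). Monocyte markers fell in 6 of 15 (median -0.49, adjusted p = 0.0035), CSF1R among them at -0.93, and leukemia cell markers in 5 of 9 (median -0.38, adjusted p = 0.0034), SPN among them at -1.38. With the preset correlation only, 7 more lists were called. Immediate early genes rose in 16 of 25 and fell in 2, FOS by 1.39 (median 0.46, adjusted p = 6.7e-07, adjusted p = 0.064 with an estimated correlation). Class I genes rose in 11 of 17 and fell in 1 (median 0.23, adjusted p = 8.4e-05, adjusted p = 0.085 with an estimated correlation), and class II genes fell in 6 of 14 (median -0.12, adjusted p = 0.031, adjusted p = 0.19 with an estimated correlation). Hypoxia and glycolysis genes fell in 16 of 29 and rose in 6 (median -0.18, adjusted p = 0.0053, adjusted p = 0.22 with an estimated correlation). Heat shock genes fell in 9 of 15 (median -0.19, adjusted p = 0.0078, adjusted p = 0.18 with an estimated correlation). Sterol genes fell in 10 of 24 and rose in 2 (median -0.14, adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation). Markers of other cell types fell in 4 of 7 (median -0.55, adjusted p = 0.016, adjusted p = 0.17 with an estimated correlation). Aryl hydrocarbon receptor targets were not called (1 higher and 3 lower of 7, median -0.11, mean of opposite sign, adjusted p = 0.66). Median, mean and test also differed in sign for uncalled interferon, iron, LXR, glucocorticoid and p53 lists.

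Licorice 125 raised CXCL2 by 3.02 ± 0.11, CXCL8 by 1.91 ± 0.11 and TNFAIP6 by 1.82 ± 0.10, and ENC1 fell by 1.15 ± 0.11, ONECUT2, a homeobox factor, by 0.96 ± 0.18 and SASH3 by 0.95 ± 0.08. It called 1367 genes, 731 higher and 636 lower, 2157 with only these 6 libraries, 3077 without the 2 atypical libraries and 835 without vehicle replicate 3. NF-kB targets rose in 18 of 24 and fell in 1 (21 and 1 alone, median 0.6, adjusted p = 5.7e-39). Between doses MT1E was higher at 500 by 5.20 ± 0.23, MT2A by 5.17 ± 0.17 and MT1X by 4.47 ± 0.19, and SCIMP was lower by 2.11 ± 0.10, SASH3 by 1.76 ± 0.10 and SLA by 1.63 ± 0.09. That comparison called 3843 genes, 1904 higher and 1939 lower, and 5988 without the 2 atypical libraries. Unfolded protein response genes were higher at 500 in 16 of 20 (17 alone, median 0.25, adjusted p = 2.5e-12) and IL-4 response genes lower in 13 of 19 by either adjustment (median -0.39, adjusted p = 2.2e-08).

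Each ingredient at 500 was then compared with the mean of the other 3, which asks what sets it apart (3 libraries against 9). A difference here may come from the other ingredients and is not a change from vehicle. Against vehicle, astragalus had 1100 genes called and atractylodes 384. Ginseng was higher in CCL15 by 3.72 ± 0.25, CCL20 by 3.04 ± 0.09 and CXCL3 by 2.66 ± 0.09. It was lower in SYTL1 by 1.59 ± 0.09, LRRC2, a protein of cardiac and muscle mitochondria, by 1.48 ± 0.10 and the kinase MAP2K6 by 1.37 ± 0.08. Astragalus was higher in RNF125 by 1.12 ± 0.10, FCGR1BP by 1.00 ± 0.08 and the pseudokinase TRIB2 by 0.96 ± 0.07. In all 3 genes its libraries overlapped vehicle. RNF125 lay at 5.767 to 6.619 CPM with astragalus, 6.464 to 9.03 in vehicle and 1.913 to 2.316 with ginseng and licorice. Astragalus was lower in MT2A by 3.97 ± 0.13, MT1G by 3.90 ± 0.21 and MT1E by 3.44 ± 0.15. Atractylodes was higher in MT1G by 2.12 ± 0.13, MT2A by 1.97 ± 0.09 and MT1E by 1.80 ± 0.11. It was lower in the myosin MYO1G by 1.00 ± 0.09, the DNA repair gene NBN by 0.92 ± 0.13 and the protease inhibitor SERPINE2 by 0.89 ± 0.06. In all 3 of these genes atractylodes nevertheless lay above vehicle, NBN at 102.3 to 108.7 CPM against 86.44 to 93.58. Licorice was higher in NHS, a regulator of actin, by 1.76 ± 0.14, IL23A by 1.74 ± 0.10 and SLC30A4-AS1 by 1.68 ± 0.10. It was lower in SCIMP by 2.15 ± 0.09, RAB7B, a GTPase of late endosomes, by 1.66 ± 0.06 and FGL2 by 1.64 ± 0.16. The counts were 5309 for ginseng (2532 higher, 2777 lower), 4156 for astragalus (2190 and 1966), 3102 for atractylodes (1770 and 1332) and 6285 for licorice (3127 and 3158). With only those 12 libraries astragalus had 6442 and atractylodes 5528, and without the 2 atypical libraries 6391 and 5434. Library totals as scale moved the share higher from 47.7% to 32.2% for ginseng and from 52.7% to 67.3% for astragalus.

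The mixture was compared with vehicle to ask whether the 4 ingredients together act on these genes. MT2A rose by 5.98 ± 0.19, from 0.409 ± 0.174 to 25.2 ± 0.45 CPM (n = 3 and 3, adjusted p = 1.92e-20), MT1E by 5.47 ± 0.25 and MT1X by 5.10 ± 0.21. CXCL2 rose by 4.18 ± 0.11, CXCL8 by 2.99 ± 0.12 and IL1B by 2.85 ± 0.06. SASH3 fell by 1.76 ± 0.09, SDS by 1.53 ± 0.11, ENC1 by 1.52 ± 0.11 and RNF125 by 1.36 ± 0.13. RN7SL2, the RNA of the signal recognition particle and nearly identical to RN7SL1, fell by 1.255 ± 0.442 but was not called by limma (adjusted p = 0.0649) or in 5 of 6 fits that left out a library. The count was 3673 genes, 1739 higher and 1934 lower, and 5571 without the 2 atypical libraries. With the mixture 21 of 24 NF-kB targets rose and 1 fell (22 and 1 alone, median 1.1, adjusted p = 7.9e-35). Immediate early genes rose in 20 of 25 and fell in 2 (median 0.43, adjusted p = 5.0e-16), and chemokine genes rose in 11 of 16 and fell in 3 (median 1.6, adjusted p = 1.3e-11), both by either adjustment. Maturation genes rose in 15 of 22 and fell in 1 (17 and 2 alone, median 0.39, adjusted p = 1.3e-10). CD80 was at 2.19 ± 0.14, CCR7 at 1.21 ± 0.24 and CD83 at 0.39 ± 0.05, and CD86 fell by 0.47 ± 0.07. Of 9 metallothionein and metal response genes 7 rose, MTF1 among them by 0.243, and SLC39A10 fell (median 5.1, adjusted p = 2.4e-09), and with MT1M at its bound of at least 5.71-fold the median is 2.51.

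Cytokine genes rose in 10 of 15 with the mixture and fell in 2 (10 and 3 alone, median 0.62, adjusted p = 3.7e-08). Aryl hydrocarbon receptor targets rose in 4 of 7 and fell in 1 (6 and 1 alone, median 0.2, adjusted p = 0.00058), CYP1B1 and TIPARP among those that rose. Lysosome genes fell in 11 of 26 and rose in 1 (12 and 2 alone, median -0.18, adjusted p = 3.7e-05), and LXR and PPAR targets fell in 8 of 22 and rose in 2 (9 and 2 alone, median -0.18, adjusted p = 0.023). Monocyte markers fell in 6 of 15 (median -0.39, adjusted p = 0.00011) and leukemia cell markers in 6 of 9 (median -0.39, adjusted p = 0.00011). With the preset correlation only, 6 more lists were called. NRF2 targets rose in 9 of 24 and fell in 3 (10 and 3 alone, median 0.11, adjusted p = 0.009, adjusted p = 0.056 with an estimated correlation). Class I genes rose in 6 of 17 (8 higher and 1 lower alone, median 0.097, adjusted p = 0.011, adjusted p = 0.26 with an estimated correlation). Of the mitochondrially encoded transcripts 1 of 13 rose (0 alone, median 0.21, adjusted p = 0.013, adjusted p = 0.48 with an estimated correlation). IL-4 response genes fell in 9 of 19 and rose in 2 (9 and 3 alone, median -0.22, adjusted p = 0.0095, adjusted p = 0.093 with an estimated correlation). Heat shock genes fell in 6 of 15 (6 lower and 1 higher alone, median -0.11, adjusted p = 0.041, adjusted p = 0.3 with an estimated correlation). Markers of other cell types fell in 2 of 7 (median -0.38, adjusted p = 0.042, adjusted p = 0.24 with an estimated correlation). Median, mean and test differed in sign for the uncalled matrix list. Every list called in this text without a second p beside it kept its call under an estimated correlation.

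**Figure D3:**
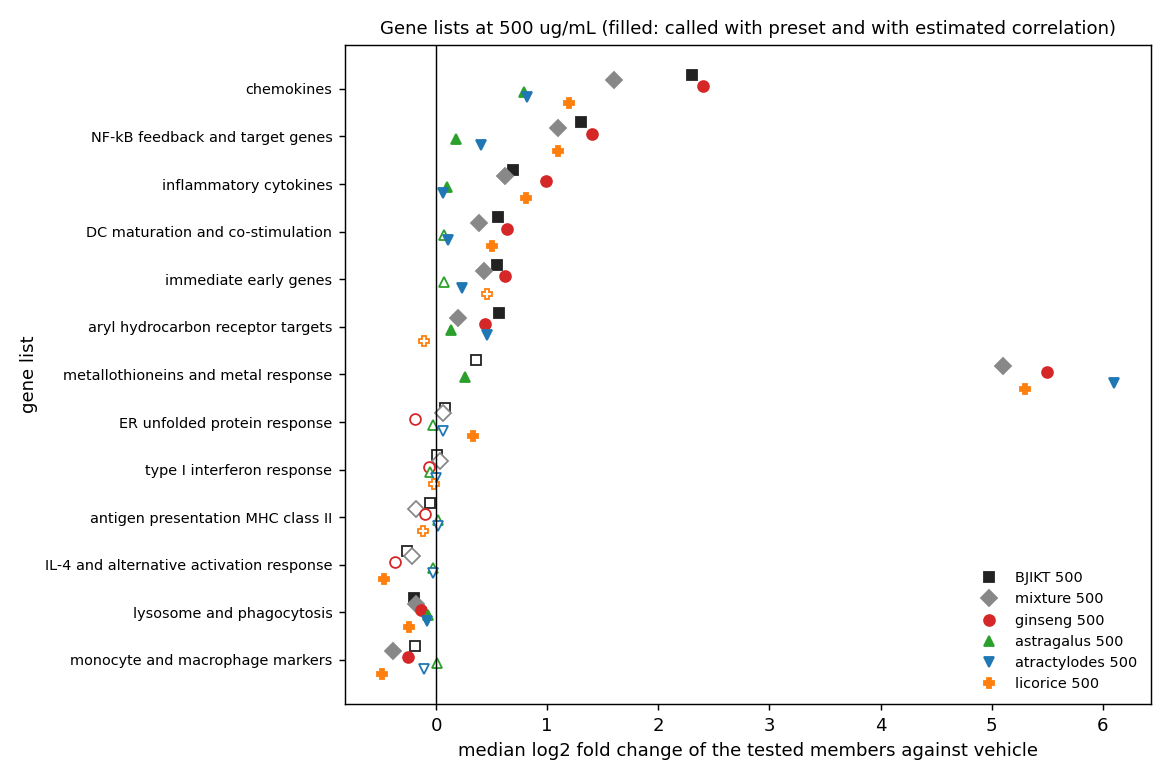
Median log2 fold change of gene lists at 500 µg/mL against vehicle, with filled symbols for lists called under both correlations. With MT1M at its lower bound the metallothionein medians are 2.7 for ginseng, 3.32 for atractylodes, 2.89 for licorice and 2.51 for the mixture.

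The mixture and BJIKT at equal total dose were compared directly to ask whether the 4 ingredients match the whole prescription. The labels do not give the share of each ingredient in BJIKT, so ingredient dose and further constituents cannot be told apart here. Metallothionein genes were higher in the mixture: MT1X by 3.69 ± 0.18, MT1E by 3.57 ± 0.19 and MT2A by 3.20 ± 0.14, at 25.2 ± 0.45 against 2.75 ± 0.16 CPM (n = 3 and 3, adjusted p = 2.19e-16). HES2, a transcriptional repressor, was higher by 0.57 ± 0.10, MAP2K6 by 0.53 ± 0.09 and the antisense gene SUGCT-AS1, uncertain, by 0.51 ± 0.11, which lost its call without BJIKT 500 replicate 3 (adjusted p = 0.0506). Cytokine and chemokine genes were lower in the mixture: CXCL3 by 1.47 ± 0.11, IL1B by 1.19 ± 0.05, LIF by 1.06 ± 0.10, CXCL8 by 0.87 ± 0.11, TNF by 0.72 ± 0.06 and CXCL2 by 0.71 ± 0.09. PDE4B, a phosphodiesterase that degrades cyclic AMP, was lower by 0.92 ± 0.11. RN7SL2 and RN7SL1 were lower by 2.65 ± 0.44 and 2.21 ± 0.44, but they are nearly identical in sequence. A single library set the BJIKT means of 79.4 ± 87.4 and 50.3 ± 54.0 CPM, and RN7SL1 was not called without BJIKT 500 replicate 1 (-0.83, adjusted p = 0.147). Of the maturation genes, EBI3 was lower by 0.54 ± 0.07 and CD40 by 0.33 ± 0.06. CD80 at -0.41 ± 0.11 and the monocyte receptor CD14 at -0.29 ± 0.08 were called (adjusted p = 0.0354 and 0.0342) but lost it with library totals as scale (adjusted p = 0.0532 and 0.0776) and in 6 and 5 of the 6 fits that left out a library. The count was 582 genes, 248 higher and 334 lower, with 1647 when only these 6 libraries were fitted, 1853 without the 2 atypical libraries and 263 without BJIKT 500 replicate 2. Library totals as scale turned the split to 301 higher and 228 lower, 56.9% higher in place of 42.6%.

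NF-kB targets were lower in the mixture than in BJIKT in 16 of 24 and higher in none (19 alone, median -0.25, adjusted p = 8.1e-28), TNIP1, which binds TNFAIP3, by 0.39 ± 0.05 and NFKBIZ by 0.51 ± 0.07. Chemokine genes were lower in 8 of 16 by either adjustment (median -0.67, adjusted p = 4.6e-17) and aryl hydrocarbon receptor targets in 5 of 7 (6 alone, median -0.37, adjusted p = 1.4e-14), TIPARP by 0.65. Metallothionein and metal response genes were higher in 6 of 9 (7 and 1 lower alone, median 3.2, adjusted p = 1.2e-21), and with MT1M at its bound of at least 6.02-fold the median is 2.59. Cytokine genes were lower in 6 of 15 and higher in 1 (median -0.17, adjusted p = 6.7e-09), and immediate early genes lower in 6 of 25 (12 and 2 higher alone, median -0.15, adjusted p = 1.1e-07). Maturation genes were lower in 7 of 22 (10 and 2 higher alone, median -0.21, adjusted p = 1.9e-06), and hypoxia and glycolysis genes in 3 of 29 (median -0.076, adjusted p = 4.5e-06). Glucocorticoid receptor targets were lower in 3 of 11 (median -0.099, adjusted p = 0.00052), sterol genes in 1 of 24 (median -0.088, adjusted p = 0.00041) and NRF2 targets in 4 of 24 (5 alone, median -0.069, adjusted p = 0.0025). Matrix genes were lower in 5 of 22 and higher in 1 (7 and 4 alone, median -0.11, adjusted p = 0.00055), and pattern recognition genes lower in 4 of 22 and higher in 1 (6 and 3 alone, median -0.097, adjusted p = 0.012). TLR4 was the receptor that was higher, by 0.79, and PPARG and PLIN2 were the 2 of 22 LXR and PPAR targets that were higher, by 0.41 and 0.38 (median 0.084, adjusted p = 0.0083). With the preset correlation only, 3 more lists were called. Class I genes were lower in 1 of 17 (4 alone, median -0.079, adjusted p = 0.0011, adjusted p = 0.15 with an estimated correlation). Mitochondrially encoded transcripts had 0 of 13 called (median 0.19, adjusted p = 0.00063, adjusted p = 0.32 with an estimated correlation). Lysosome genes were higher in 2 of 26 and lower in 3 (5 and 3 alone, median 0.046, adjusted p = 0.047, adjusted p = 0.14 with an estimated correlation). Median, mean and test differed in sign for uncalled interferon, IL-4, stress response, monocyte and other cell type lists.

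The mixture was set against its parts to ask whether they add up on the log2 scale. Its log2 change from vehicle was compared with the sum of the 4 log2 changes at 125 µg/mL. Summing log2 changes multiplies fold changes. A gene lower than this sum can still reach the sum of its rises in CPM, which was not tested. Against the sum of log2 changes 17 genes were lower and 0 higher, of 1254 with an unadjusted p under the same level. The summed CPM of 6 MT1 and MT2 genes was 52.1 with the mixture, against 1.84 to 3.27 with single ingredients at 125 µg/mL. The median log2 change of these genes from vehicle was 5.54 with the mixture. It was 0.967 with ginseng 125, 0.0296 with astragalus 125, 1.08 with atractylodes 125 and 0.692 with licorice 125. None of these genes was called higher than the sum of log2 changes. Their summed CPM was only 1.89 in vehicle, so the missing call does not show that they add up. CXCL2 was lower by 3.10 ± 0.32, ZC3H12A by 1.98 ± 0.22 and TNFAIP6 by 1.77 ± 0.27. TNFAIP6 lost its call without vehicle replicate 3 (-1.31, adjusted p = 0.0632). In CPM, CXCL2 lay at 65.18 to 66.81 with the mixture, 30.66 to 38.04 with ginseng 125 and 28.08 to 30.66 with licorice 125. With astragalus or atractylodes 125 it lay at 4.117 to 5.844. The count was 39 by DESeq2, 44 with no filter, 102 without the 2 atypical libraries, 9 without vehicle replicate 3 and 45 without astragalus 125 replicate 3. Some of these fits also had genes higher, 24 of the 102, 8 of the 44, 6 of the 45 and 3 of the 39. Across genes the difference from the sum followed GC content at a Spearman correlation of -0.322.

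Changes from vehicle were correlated across 17776 genes to ask which treatment resembles BJIKT 500. These genes are not independent replicates, and the shared vehicle libraries alone give a simulated correlation near 0.5. BJIKT correlated at 0.789 with ginseng (0.513 simulated), 0.723 with the mixture (0.502), 0.679 with licorice (0.507), 0.53 with atractylodes (0.504) and 0.5 with astragalus (0.505). Covariance above the simulated value was 0.174 for ginseng, 0.154 for licorice, 0.121 for the mixture, 0.0521 for astragalus and 0.0478 for atractylodes. Covariance also grows with the size of the changes, so its order is not an order of resemblance. The 3 vehicle libraries cannot be split into 2 parts of at least 2 libraries, so part of this excess may still come from the shared vehicle. Of these groups only ginseng 500 shares the code of BJIKT and vehicle. The simulation held no code effect, so the order of the groups may partly follow the code. Rank correlation lowered the value to 0.399 for astragalus. CXCL2, IL1B and TNF were among 1758 genes higher with both BJIKT and ginseng (284 if independent), and 1952 were lower with both (362). With the mixture 1395 were higher in both (208) and 1520 lower in both (260), with licorice 1487 (395) and 1709 (444), with astragalus 295 (65) and 361 (74), and with atractylodes 253 (32) and 112 (16). Other genes were called in opposite directions. Those higher with BJIKT but lower with the other treatment numbered 41 for licorice, 24 for astragalus, 1 for the mixture and 0 for ginseng and atractylodes. The reverse held for 44, 19, 0, 1 and 0 genes with licorice, astragalus, the mixture, ginseng and atractylodes. Independence is not the value without resemblance here, since both changes share the vehicle libraries, so these overlaps are counts and not a test of resemblance. The mixture correlated at 0.68 with the sum of its ingredients at 125 (0.636 simulated), with a covariance excess of 0.174.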

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

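The items listed next came out of a tested difference between the mixture and BJIKT at 500 µg/mL. MT1X (3.69), MT1E (3.57) and MT2A (3.2) were higher in the mixture, as was the metallothionein list (median 3.2). CXCL3 (-1.47), IL1B (-1.19) and LIF (-1.06) were lower, as was the chemokine list (median -0.675). RN7SL2 (-2.65) and RN7SL1 (-2.21) were lower too, with the BJIKT mean set by a single library.

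All tests of the metallothionein difference were chosen after the result was seen. The MT1 and MT2 genes were higher in the mixture than in BJIKT at equal total dose. The first test of the label code took the median of the called genes in atractylodes 125 against vehicle, 1.08, with too wide a spread between genes (SD 0.789) to decide. A second, made after that result, compared summed CPM and gave 0.797 (SD 0.21) there and 0.542 (SD 0.327) in licorice 125, against 3.2 for the mixture over BJIKT and 3.62 for ginseng 500 over BJIKT within 1 code, which argues against the code. A summed ratio of 3.19 argues against reads only moving between paralogs, and a median of -0.136 for FKBP5, TSC22D3, PER1 and KLF9 argues against glucocorticoid activity. Metal load stays open, since the zinc exporter SLC30A1 was at 0.576 ± 0.229 (adjusted p = 0.204, edgeR, n = 3 and 3), which came from a fall with BJIKT (-0.672, adjusted p = 0.0287) and not from a rise with the mixture (-0.0959 from vehicle, adjusted p = 0.836).

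Both tests of the NF-kB difference were written before their values were seen. NF-kB targets were lower in the mixture than in BJIKT. The median in atractylodes 125 against vehicle, which crosses the same codes, was 0.115, above 0 as the test set for excluding the code. That bound was wrong, since extracts raise these genes (median 0.64 in BJIKT 125, within the code of vehicle) and can hide a fall, so the code stays open. Thinning all libraries to one total left the median at -0.254. Thinning keeps the expected share of each gene, so it could hardly move this median and does not decide about depth. What the further constituents of BJIKT or the dose of each ingredient in it do was not tested and stays open.

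The 3 tests of astragalus 125 replicate 3 were written before their values were seen. This library lay 0.687 from its replicates, with GMFB and TMED7 far lower in it. Depth is argued against, since its replicates thinned to its total lay 0.4 apart. A swapped label stays open, since the nearest other group mean lay at 0.667, above the bound of 0.404 set for excluding it, but a library that deviates along GC lies far from every group whatever its label. GC content followed its deviation at a Spearman correlation of 0.696, as that test stated in advance, against at most 0.267 in the other 33 libraries so measured. Whether this arose in library preparation or sequencing stays open.

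Splits of the same libraries, written before their values were seen, were compared by their counts of called genes. With 3 libraries against 3 there are too few splits (10, the real one included). The real split alone reached its count, 1 of 10, for all such comparisons except astragalus 125, with 2 of 10 (highest other 285). The highest other count was 1 for ginseng 125 and for the BJIKT doses, and 0 for the rest. For single ingredients against the others, 1 (ginseng), 1 (astragalus), 2 (atractylodes) and 1 (licorice) of 100 splits reached the count, with highest others of 1215, 2325, 3946 and 4017, which argues against chance among the 12 libraries. These splits exchange libraries between groups that differ, so they do not show that a count belongs to that ingredient. For the mixture against the sum, 11 of 100 did, with a highest other of 3444, far above the real 17, which points to structure among these groups, and chance stays open there.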

How the results depend on the processing

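No named gene changed sign where it was called before or after, though uncalled ones near 0 did (HLA-DRA in atractylodes 125, -0.0452 and 0.0807 without vehicle replicate 2). Of 6030 values of named genes 5873 kept their label, 121 were weaker and 36 stronger. The majority of higher or lower calls did turn in places. BJIKT 125 had 510 higher and 753 lower with library totals (664 and 550 reported), and the mixture against BJIKT 301 and 228 (248 and 334). Astragalus 125 had 89 and 120 with RLE factors and 181 and 739 with no filter (101 and 80), and its doses 989 and 203 with no filter (139 and 180). Further splits turned as well, among them licorice 125 with library totals (627 and 718 for 731 and 636). Settings without the 2 atypical libraries were added after the data were seen, and the cause of each move was not tested. The tolerance for correlations was also set after they were seen: by the jackknife error first planned 30 of 48 values moved, by the largest move on leaving out a vehicle library 8 did.

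With only the compared libraries, counts were 513 (BJIKT 125), 1255 (ginseng 125), 2086 (astragalus 500), 0 (astragalus 125), 736 (atractylodes 500), 84 (atractylodes 125), 2157 (licorice 125), 4979, 0 and 409 (doses of ginseng, astragalus and atractylodes), 1647 (mixture against BJIKT), 6442 (astragalus against others) and 5528 (atractylodes against others). Without the 2 atypical libraries they were 1936 (ginseng 125), 3014 (astragalus 500), 524 (astragalus 125), 1226 (atractylodes 500), 229 (atractylodes 125), 3077 (licorice 125), 5571 (mixture), 4825, 186, 434 and 5988 (doses of ginseng, astragalus, atractylodes and licorice), 1853 (mixture against BJIKT), 6391 and 5434 (astragalus and atractylodes against others) and 102 (mixture against sum).

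With no filter, counts were 920 (astragalus 125), 89 (atractylodes 125), 1192 (astragalus doses) and 44 (mixture against sum). At a mean CPM of at least 5 they were 362 (astragalus 125) and 505 (astragalus doses), and by DESeq2 642, 66, 717 and 39. Replicate numbers did not pair the samples (mean r 0.0042 for the same number, -0.0021 for different numbers), though 20 of 36 libraries correlated best with their own number, and the block gave 29 for mixture against sum.

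Lists called with an estimated correlation numbered 7 (astragalus 500), 2 (astragalus 125), 12 (licorice 500), 11 (mixture), 10, 5 and 10 (doses of ginseng, astragalus and licorice). Correlations with BJIKT were 0.892 (mixture), 0.941 (ginseng), 0.659 (atractylodes) and 0.774 (licorice) at a mean CPM of at least 5, and 0.803 for mixture against sum. By Spearman they were 0.807 (ginseng), 0.399 (astragalus) and 0.623 (licorice).

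Leaving out a library gave 740 to 1560 (BJIKT 125), 526 to 690 (ginseng 125), 628 to 767 (astragalus 500), 46 to 2534 (astragalus 125), 170 to 366 (atractylodes 500), 5 to 29 (atractylodes 125), 835 to 1179 (licorice 125), 1808 to 2751 (BJIKT doses), 53 to 3399 (astragalus doses), 57 to 67 (atractylodes doses), 263 to 441 (mixture against BJIKT) and 9 to 45 (mixture against sum).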

Other observations

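Some genes were lower than vehicle in all 6 treatments at 500 µg/mL (n = 3 and 3, edgeR, chosen after their values were seen). All 6 comparisons use the same 3 vehicle libraries, so their shared direction is not independent evidence, and how often chance would give it was not tested. F13A1, a transglutaminase of alternatively activated cells, fell by 2.85 with BJIKT, 2.58 with ginseng, 1.11 with astragalus, 1.37 with atractylodes, 3.26 with licorice and 2.61 with the mixture. GDF15, a stress cytokine, fell by 0.86, 0.71, 0.51, 0.29, 0.70 and 0.60 in the same order, and CXCR4, a receptor for homing to bone marrow, by 0.55, 0.51, 0.28, 0.23, 0.66 and 0.37. The weakest calls for these 2 genes were with atractylodes (adjusted p = 0.0108 for GDF15 and 0.0155 for CXCR4).

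The summed CPM of 6 MT1 and MT2 genes was 1.89 ± 0.265 (mean ± SD) in vehicle, 5.7 ± 0.49 with BJIKT 500, 69.9 ± 4.5 with ginseng 500, 7.18 ± 1.64 with astragalus 500, 107.4 ± 9.12 with atractylodes 500, 60.4 ± 4.07 with licorice 500 and 52.1 with the mixture. At 125 µg/mL it lay between 1.84 and 3.27. A hypothesis is that the ginseng, atractylodes and licorice extracts and the mixture carried more available zinc or copper than the BJIKT extract, and metal load was left open by SLC30A1 at 0.576. Against vehicle this zinc exporter was not called higher by edgeR. It was at -0.0959 ± 0.227 with the mixture, 0.065 ± 0.226 with ginseng, 0.352 ± 0.226 with atractylodes (adjusted p = 0.643) and -0.445 ± 0.228 with licorice. This does not favor the hypothesis, but it rests on a single gene whose SE leave a moderate rise possible. The zinc importer SLC39A10 was called lower with the mixture (-0.506), ginseng (-0.364), atractylodes (-0.512) and licorice (-0.633). It was also called lower with BJIKT (-0.445), so it does not separate BJIKT from them. Measuring both metals in each extract and adding a chelator before treatment would test it.

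A second hypothesis is that constituents of BJIKT beyond these 4 ingredients raise NF-kB targets, whose median was -0.254 in the mixture against BJIKT after thinning. Adding the remaining herbs to the 4 ingredients in their BJIKT proportions, with replicates spread over the label codes, would test it.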
